A study of Mus musculus with 9 samples.

How the data were processed

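The series holds 9 single-cell RNA-seq libraries from the livers of mice, 3 per group: wild type (WT), a whole-body CFTR knockout (CFTR-KO), and the knockout with CFTR restored in the gut (CFTR-KO-GC). The animals were 8 weeks old. Per the labels' protocols, livers were perfused with collagenase, the gallbladder and the hilum were removed, most of the released hepatocytes were discarded, the remaining tissue was digested in steps, and 10000 cells per library were loaded for 10x Genomics 3' chemistry. The shares of cells below are therefore shares of a recovered suspension and not of the liver.

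Groups and replicate numbers were read from the sample titles. The strain fields of the WT and CFTR-KO-GC libraries look exchanged against the titles and the group fields, so the strain fields were not used. No sample was left out. All cells of a library were assigned to its group, and no deposited annotation of cells was used here.

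The authors deposited 1 matrix of raw UMI counts per library, written by Cell Ranger and not normalized, per the file headers. Those headers give Cell Ranger 5.0.1 for replicate 1 of every group and 7.1.0 for replicates 2 and 3. The submitters' processing notes name Cell Ranger 3 and the mm10 build instead. The values of the files are whole numbers, and the lowest total of any barcode was 500 UMIs, so a filter on barcodes had been applied before deposit. Neither source says whether intronic reads were counted. Each library had 32285 features, all of them gene expression features. Gene positions below are from the GENCODE M21 annotation of mm10, in which 32158 of the features have an entry.

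Cells were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs, which left 56690 cells. Doublets were scored with Scrublet as built into scanpy 1.11.5, and in each library the highest scores were removed at a rate of 0.8% per 1000 barcodes, which left 51544 cells. CFTR-KO replicate 1 held 14306 barcodes and CFTR-KO replicate 2 held 16762, both above the number of cells loaded per the labels. Counts were scaled to 10000 UMIs per cell and log-transformed. Components were computed on 2000 variable genes, 30 components were kept, and cells were joined to 20 neighbours and clustered with leidenalg 0.10.2 at resolution 1. A first clustering separated the same cell types by Cell Ranger version. Genes were therefore scaled within each version, and the components were corrected for the version with a Harmony procedure of 60 soft clusters, a penalty of 2 and 8 rounds. Differences between libraries of the same version were not corrected. This correction was chosen after seeing the clusters and touches the class labels only, never the counts tested. Clusters 10, 31 and 35 each held cells of more than 1 type and were split at resolution 0.3, also after looking at them.

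A cluster was named "X-like" only from the markers fixed in advance, with at least 3 of them detected in at least 10% of its cells and its 10 leading genes by fold not going against the name. This gave 22 named classes, and 15 of the 49 clusters, with 14048 cells, stayed unnamed. Most of those were droplets of few UMIs carrying hepatocyte transcripts; the rest were cycling cells and small mixed clusters. Lcn2, Cxcl5, Cd14 and Ubd were among the leading genes of 1 of the cholangiocyte-like clusters. The largest cluster of a class, over the pooled cells of a group, differed between groups in 3 tested classes. Among B-like cells sub-cluster 0 of cluster 10 was the largest in CFTR-KO-GC and sub-cluster 1 in WT and CFTR-KO. Among hepatocyte-like cells it was cluster 14 in CFTR-KO and cluster 23 in WT and CFTR-KO-GC, and among vascular endothelial-like cells cluster 11 in WT and cluster 13 in CFTR-KO and CFTR-KO-GC. Per library, sub-cluster 0 was the larger of the 2 B-like ones in every 5.0.1 library and sub-cluster 1 in every 7.1.0 library. Cluster 14 held 159 and 172 cells of WT and CFTR-KO-GC replicate 2, female by sex-linked transcripts, and cluster 23 held 1 and 2. In the male WT and CFTR-KO-GC libraries cluster 14 held 0 to 8 cells and cluster 23 held 80 to 328. Male CFTR-KO replicate 1 held 116 and 0. These pooled differences thus partly follow version and sex. For cholangiocyte-like cells the pooled largest cluster was cluster 3 in every group, but this hides a difference among the number 1 libraries. Cluster 7 held 1956 of the 2024 cholangiocyte-like cells of CFTR-KO replicate 1, while cluster 8 held 932 of 934 in WT replicate 1 and 522 of 555 in CFTR-KO-GC replicate 1.

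Cells are not replicates, so UMI counts were summed per library and class. A library entered a class with at least 20 cells, and a class was tested with at least 2 such libraries in every group, which left 16 classes. All tested classes had 3 libraries per group except the B-like cells (without WT replicate 1), the dendritic type 2-like cells (without WT replicate 3), the gamma-delta T or innate lymphoid-like cells (without CFTR-KO-GC replicate 3) and the natural killer-like cells (without CFTR-KO-GC replicate 2). The sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM factors and all 3 groups in 1 fit without covariates, which leaves 6 residual degrees of freedom in a class with all libraries. P-values were adjusted by Benjamini-Hochberg within class and comparison, and an adjusted p under 0.05 was called. Standard errors of log2 fold changes are the fold change divided by the root of the F statistic. CPM values are the sums of a class over its TMM-normalized library size, given as mean ± SD over the libraries of a group. A test over all 3 groups was run in the cholangiocyte-like, sinusoidal endothelial-like, Kupffer-like and hepatic stellate-like classes; the monocyte-like class had been planned for it as well but had too few cells. Numbers of cells per class were tested with edgeR against the total of kept cells. Gene lists, 28 in all and fixed in advance, were tested with camera in limma 3.58.1 with the preset correlation of 0.01 where at least 5 members were tested.

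All designs, lists, markers, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Cftr, the 3 higher and 3 lower genes with the largest fold among called genes of at least 20 mean CPM without overlap between the groups' libraries in the 4 classes with most calls, up to 4 called members of each list with the smallest p, and up to 5 genes called in the most classes. Where a comparison has no called gene, it names the 5 genes with the smallest p. The rule was applied to the fit without covariates and, after that fit was seen to call almost nothing, also to the fit with the replicate number as a block.

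Whether the replicate numbers pair the samples was decided from the data before blocked calls were compared. In cholangiocyte-like cells the deviations from the group means correlated at 0.504 to 0.841 between libraries with the same number, and the median over the tested classes was 0.367 to 0.731 for each such pair. Every same-number pair lay above 0.1, so the numbers were taken to pair the samples, and blocked values are printed beside results that they change. Different-number pairs within version 7.1.0 lay above 0.1 too, with medians over the classes of 0.261 to 0.448. That bound therefore could not tell whether numbers 2 and 3 pair the samples. The labels do not say what the numbers share. Libraries with different numbers correlated at 0.398 to 0.647 within version 7.1.0 and negatively across versions, so much of the pairing follows the Cell Ranger version. In cholangiocyte-like cells 6961 of 13793 tested genes (50.5%) differed between the versions at an adjusted p under 0.05 in edgeR, with a median absolute log2 fold change of 0.47. By sex-linked transcripts all number 1 libraries were male, as were CFTR-KO-GC and WT replicate 3, and the other libraries were female. The version thus coincides with replicate number 1 and partly with sex, and this test does not separate them. A fit with the version as a term was therefore added after the headers were seen, and a fit with version and sex as terms after sex-linked genes showed that 1 of the 3 replicate numbers holds libraries of both sexes. The block leaves 4 residual degrees of freedom, the version term 5, and version with sex 4. No male CFTR-KO library was of version 7.1.0. With version and sex as terms, WT and CFTR-KO-GC replicate 3 therefore bear on the folds of CFTR-KO only indirectly, and these folds rest on fewer control libraries.

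Other alternatives covered DESeq2 1.42.0, other scalings, filters on genes and cells, doublets kept, a coarser clustering at resolution 0.5, equal numbers of cells, the share of hepatocyte transcripts as a covariate, camera with an estimated correlation, fry, and leaving out each library in turn. No alternative fixed in advance was left out. No 2 libraries of a group were copies of one another: the chi-square of their cholangiocyte-like sums per degree of freedom was 11.7 to 238.

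The tests were checked on simulated counts, drawn with the dispersions and the mean of each Cell Ranger version in the real sums, in which genes were raised or lowered in CFTR-KO by known folds, 40 genes per fold. For CFTR-KO against WT over the 13793 genes of cholangiocyte-like cells, the fit without covariates recovered 0% of genes raised 2-fold, 60% of those raised 4-fold and 80% of those raised 8-fold. The fit with the block recovered 87.5%, 95% and 100% of them. It also called 14 genes that had not been changed, against 0 in the fit without covariates. Depth per library was 30599587 to 75486901 UMIs in all barcodes.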

Results

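Neutrophil-like cells, recognized by their granule and chemokine-receptor transcripts, made up 7.15 ± 6.14% of the kept cells in CFTR-KO livers, against 0.311 ± 0.151% in WT and 1.06 ± 1.21% in CFTR-KO-GC (mean ± SD, n = 3 libraries per group throughout unless stated). The CFTR-KO libraries stood at 14.2, 3.67 and 3.55%, replicate 1 the highest. The log2 fold change of CFTR-KO against WT was 4.53 ± 1.04 (SE), with an edgeR adjusted p of 0.0233 over the classes, and it was the 1 class share called by the fit without covariates. An exact 2-sided permutation test of 3 against 3 cannot give a p under 0.1, and after adjustment it gave 0.367. Without CFTR-KO replicate 1 the edgeR adjusted p was 0.052, without WT replicate 1 0.123, without WT replicate 2 0.0868 and without WT replicate 3 0.177. With the replicate number as a block the adjusted p was 0.016. Against CFTR-KO-GC the log2 fold change was 2.75 ± 0.95, with an adjusted p of 0.103.

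T-like cells were 4.63 ± 2.34% of kept cells in WT, 12.3 ± 1.61% in CFTR-KO and 5.88 ± 2.62% in CFTR-KO-GC, with an edgeR adjusted p of 0.138 for CFTR-KO against WT. Among immune cells alone the log2 fold change was −0.001 (edgeR adjusted p 0.998), so T-like cells did not rise relative to the other immune cells. The difference thus depends on the denominator. All kept cells include low-UMI hepatocyte-transcript droplets, at 36.3 ± 20.6% in WT and 12.4 ± 13.1% in CFTR-KO. The test among immune cells leaves out other cells too, so it does not show that the droplets bring the difference. Natural killer-like cells were 0.551 ± 0.171%, 2.26 ± 1.31% and 0.972 ± 0.741% in the same order. Smooth muscle-like cells were 2.45 ± 1.02% in WT, 0.791 ± 0.356% in CFTR-KO and 3.80 ± 2.08% in CFTR-KO-GC, with adjusted p-values of 0.13 for CFTR-KO against WT and 0.0627 against CFTR-KO-GC. Cholangiocyte-like cells, the lining of the bile ducts, were 18.2 ± 7.77%, 18.3 ± 4.19% and 13.5 ± 3.55%. None of these shares passed the test in the fit without covariates.

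**Figure D1:**
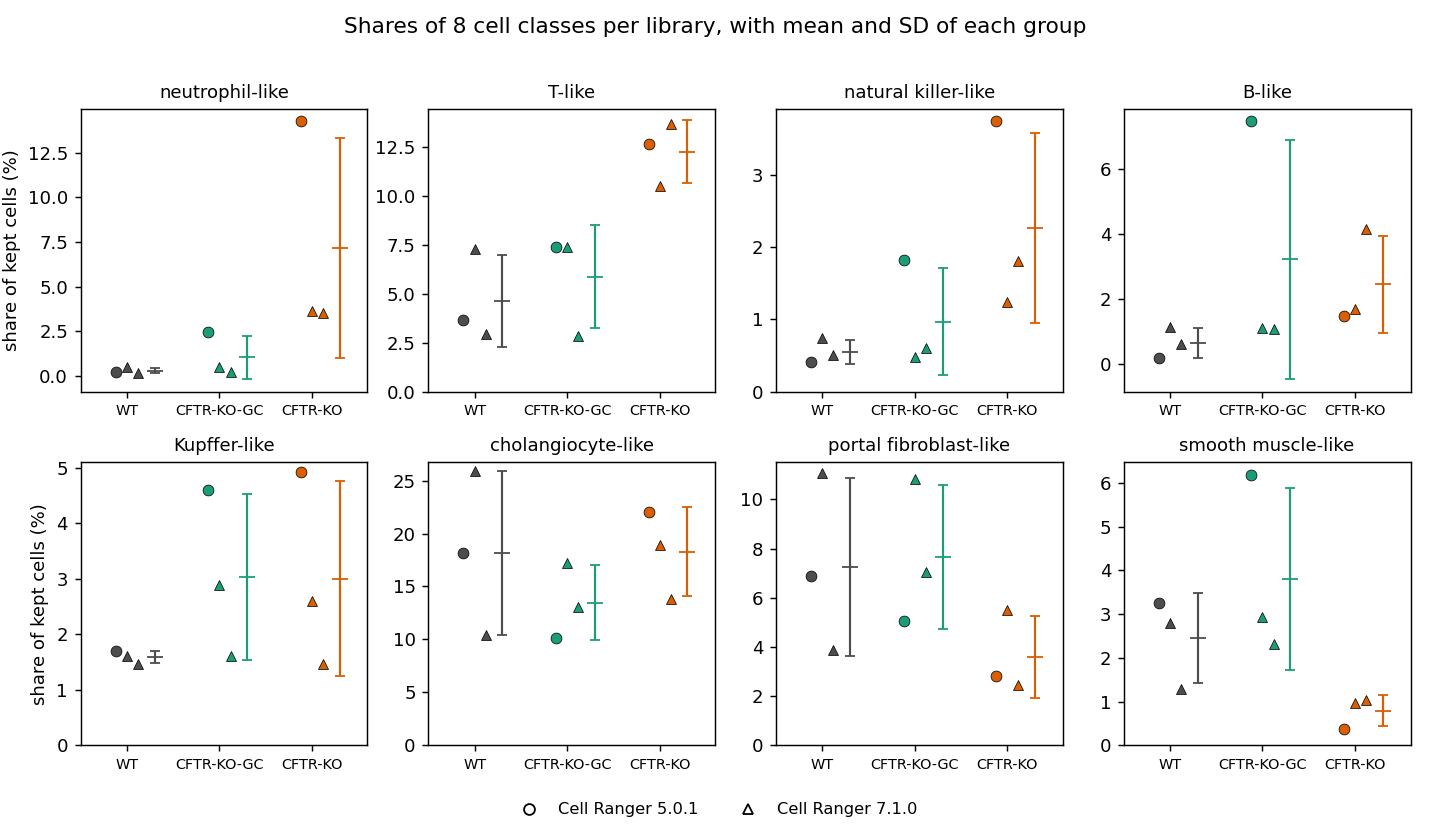
Share of kept cells (percent) of 8 cell classes in each library, by group; circles are Cell Ranger 5.0.1 and triangles 7.1.0 libraries, and bars are the mean ± SD. Neutrophil-like cells are 14.2, 3.67 and 3.55% in the CFTR-KO libraries and average 0.311% in WT.

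In cholangiocyte-like cells, MHC class II genes, which present extracellular peptides to T cells, had higher levels in CFTR-KO than in WT. The clusters of this class followed the Cell Ranger version and, within 5.0.1, set CFTR-KO replicate 1 apart. CFTR-KO replicates 2 and 3 lay mainly in cluster 3, as did the 7.1.0 libraries of WT and CFTR-KO-GC. Cluster 7, led by Sftpd, Cxcl5 and Lcn2, held 1956 cells of CFTR-KO replicate 1, 21 of replicate 2 and 63 of replicate 3, against 1 WT cell and 3 CFTR-KO-GC cells. H2-Aa stood at 692 ± 861 CPM in CFTR-KO and 15.9 ± 11.3 in WT, H2-Eb1 at 695 ± 804 and 22.9 ± 15.04, and Cd74, the chaperone of class II molecules, at 2649 ± 3006 and 107 ± 31.5. Lcn2, which encodes a siderophore-binding antibacterial protein, stood at 19642 ± 23918 CPM in CFTR-KO and 357 ± 63.1 in WT, and the neutrophil chemokine gene Cxcl5 at 1343 ± 1639 and 8.06 ± 2.80. The keratin gene Krt17 was lower in CFTR-KO, at 6.45 ± 2.43 against 28.3 ± 7.14 CPM.

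How many of these differences pass depends on the model. Without covariates edgeR called 1 gene in this class, the noncoding gene Gm20186. Of the 13793 genes tested, 1011 had an unadjusted p under 0.05, a share above the 0.05 expected with no differences. With the replicate number as a block edgeR called 234, of which 180 were higher and 54 lower in CFTR-KO, and DESeq2 without covariates called 268. The blocked count rests on single libraries. It was 115 without CFTR-KO replicate 1, 755 without CFTR-KO replicate 2 and 4 without CFTR-KO replicate 3. Without WT replicates 1, 2 and 3 it was 8, 16 and 1. All 3 number 1 libraries were made with Cell Ranger 5.0.1, and 1 of the 3 replicate numbers holds libraries of both sexes; with version and sex as terms the count was 29.

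The following folds are from the blocked fit, with its edgeR adjusted p, and each gene moved the same way in 3 of 3 pairs. H2-Eb1 rose by a log2 fold change of 4.53 ± 0.58 (SE, adjusted p 0.026), H2-Aa by 4.95 ± 0.69 (0.0289), Cd74 by 4.17 ± 0.67 (0.0333) and Ciita, the transcriptional activator of class II genes, by 3.33 ± 0.54 (0.0334). Lcn2 rose by 4.85 ± 0.74 (0.029) and Slpi, a secreted protease inhibitor, by 5.29 ± 0.88 (0.0334). Among cytokine genes Cxcl5 rose by 6.47 ± 1.02 (0.0321), Tnf by 2.38 ± 0.37 (0.0311), the macrophage growth factor gene Csf1 by 2.72 ± 0.46 (0.0345) and the interferon-induced chemokine gene Cxcl9 by 4.97 ± 0.85 (0.0345). Pigr, the transporter of IgA into bile, rose by 1.24 ± 0.17, and the adhesion gene Vcam1 by 0.98 ± 0.14. Slc4a4, a sodium bicarbonate cotransporter, went from 173 ± 69.6 CPM in WT to 360 ± 158 in CFTR-KO. Timp1, an inhibitor of matrix proteases, rose by 3.94 ± 0.66, the adhesion gene Ncam1 by 2.07 ± 0.35 and the fatty-acid carrier gene Fabp5 by 1.21 ± 0.20. Immunoglobulin transcripts (Igkc, Ighg2b, Ighg2c, Jchain), the hepatocyte transcripts Trf and Ahsg, and Gpr182 and Kit were also higher. They are abundant in other cell types, so free RNA is open for them. It is open for Slpi too, a leading gene of the mesothelial-like cluster.

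Genes that fell in the same fit include Krt17 at −2.15 ± 0.16 (adjusted p 0.00613), Krt19, a keratin of bile duct cells, at −0.86 ± 0.15 (0.0345), and the potassium channel gene Kcnn4 at −0.81 ± 0.11 (0.0289). The glycolytic gene Pkm fell by 0.91, the thromboxane synthase gene Tbxas1 by 2.94 and Smim5 by 3.47 on the log2 scale. With version and sex as terms, H2-Aa (adjusted p 0.0448), H2-Eb1 (0.043), Krt17 (0.00502), Fabp5 (0.0432), Jchain (0.0423), Ighg2b (0.0499) and Gm20186 (0.00113) still passed among the genes named here. Of those that did not, Cd74 was at 4.23 ± 0.70 (0.0631), Lcn2 at 4.71 ± 0.79 (0.0631) and Krt19 at −0.88 ± 0.17 (0.075), folds close to those of the blocked fit.

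**Figure D2:**
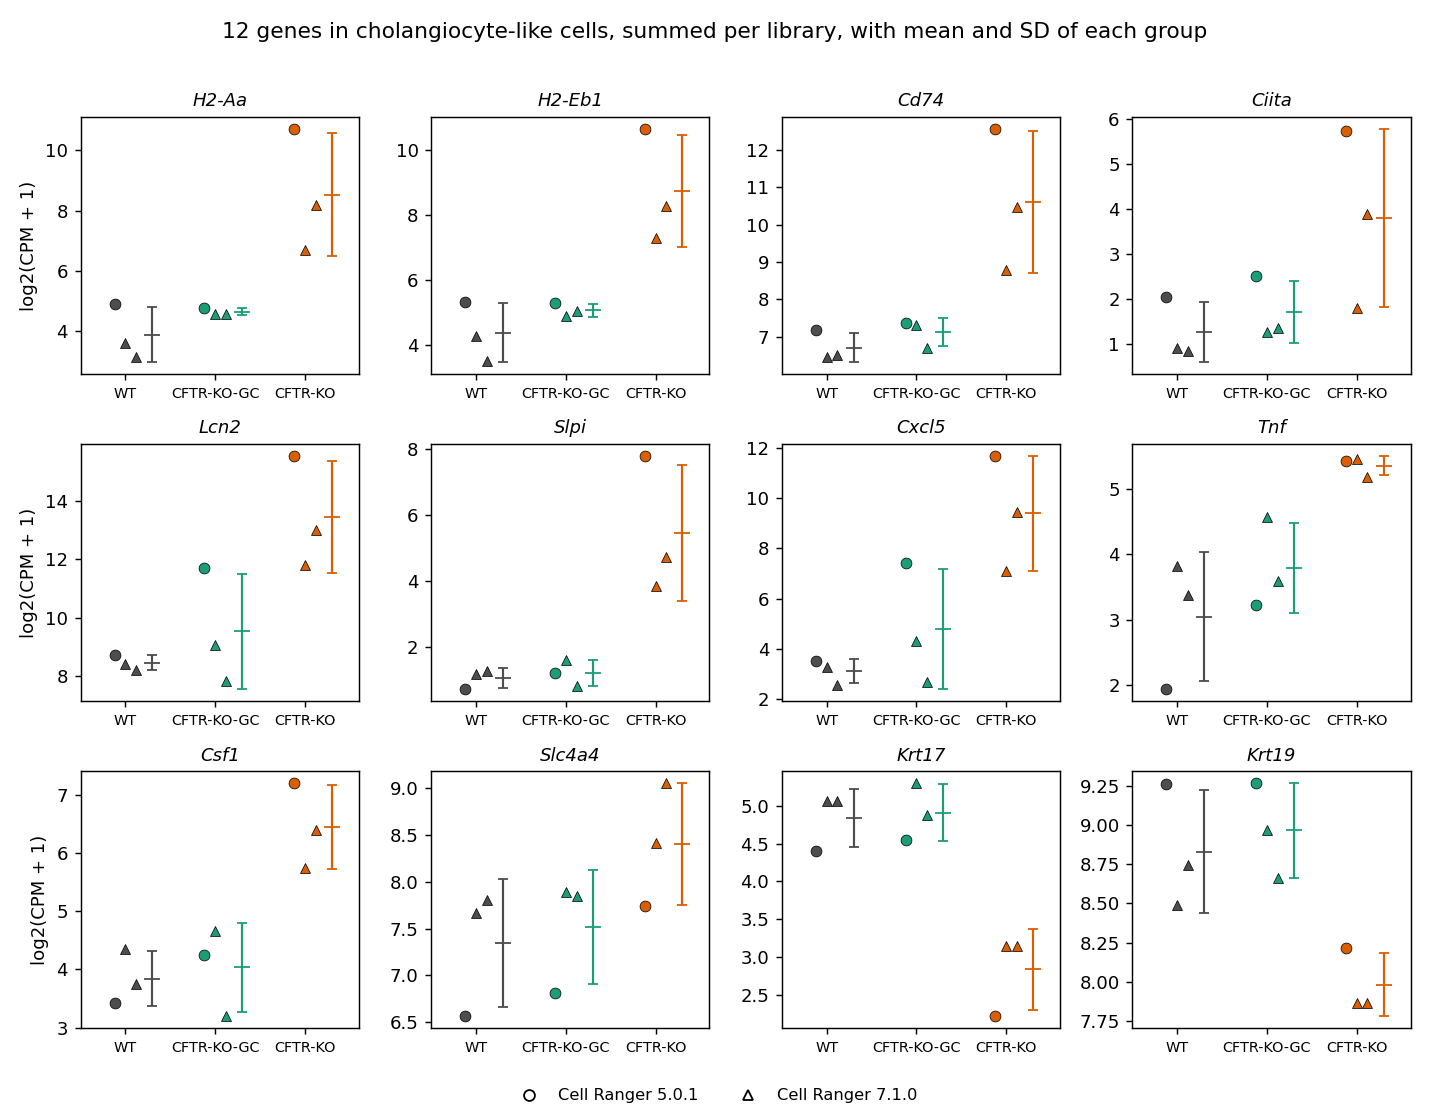
Expression of 12 genes in cholangiocyte-like cells, as log2(CPM + 1) per library and by group; circles are Cell Ranger 5.0.1 and triangles 7.1.0 libraries, and bars are the mean ± SD. Lcn2 averages 19642 CPM in CFTR-KO, 1365 in CFTR-KO-GC and 357 in WT.

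In other classes the calls of the same comparison included Lcn2 in 4 classes and Igkc in 4. Lcn2 stood at 19642 CPM in cholangiocyte-like cells of CFTR-KO and is also a neutrophil transcript, Igkc comes from plasma and B cells, and Mup11, Mup20, Orm1 and Hpx come from hepatocytes. No share of free RNA was estimated for these calls, so free RNA is open for each of them. In the sums of sinusoidal endothelial-like cells Lcn2 went from 4.57 ± 4.89 CPM in WT to 363 ± 368 in CFTR-KO, a log2 fold change of 6.15 ± 0.42 in the blocked fit (edgeR adjusted p 9.38e-05). It was also called in smooth muscle-like (4.81 ± 0.40), plasmacytoid dendritic-like (4.37 ± 0.68) and natural killer-like cells (4.14 ± 0.72). The chemokine gene Ccl5 rose by 5.04 ± 0.71 in gamma-delta T or innate lymphoid-like cells (adjusted p 0.0194). Igkc, the kappa light chain constant region, was called higher in portal fibroblast-like, smooth muscle-like, vascular endothelial-like and gamma-delta T or innate lymphoid-like cells. In plasmacytoid dendritic-like cells the acute-phase genes Orm1 (2.13 ± 0.36) and Hpx (adjusted p 0.0304) rose. Mup11 and Mup20, urinary protein genes, were called lower in natural killer-like and plasmacytoid dendritic-like cells in 2 of 3 pairs. With version and sex as terms the Mup calls were lost, as were Lcn2 in sinusoidal endothelial-like (adjusted p 0.0614), plasmacytoid dendritic-like (0.12) and natural killer-like cells (0.232), Igkc in vascular endothelial-like (0.169) and gamma-delta T or innate lymphoid-like cells (0.0689), and Hpx (0.188). Lcn2 in sinusoidal endothelial-like cells was then at 6.15 ± 0.83, the same fold with a larger error. In natural killer-like cells Mup11 went from −7.65 ± 1.11 to −6.05 ± 1.48 and Mup20 from −5.05 ± 0.77 to −4.28 ± 0.96. The loss of these calls does not show that sex explains them, but sex stays open. In replicate 3 the CFTR-KO library was female and the WT library male. Cluster 30, hepatocyte-like and led by Mup20, held 53 to 150 cells in the male WT and CFTR-KO-GC libraries. It held 0 in every female library, and also 0 in male CFTR-KO replicate 1. With version and sex as terms Lcn2 and Igkc in smooth muscle-like cells (both 0.0256), Igkc in portal fibroblast-like cells (0.0223), Ccl5 (0.0481) and Orm1 (0.0266) passed.

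Over all 16 classes the fit without covariates called 2 gene and class pairs for CFTR-KO against WT, both of them Gm20186. In that comparison 3399 of 118630 pairs had an unadjusted p under 0.05, a share under the 0.05 expected with no differences. The blocked fit called 257 and DESeq2 388. The blocked count was 141 without CFTR-KO replicate 1, 1858 without CFTR-KO replicate 2 and 13 without CFTR-KO replicate 3, and 23, 103 and 10 without WT replicates 1, 2 and 3.

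Between CFTR-KO and CFTR-KO-GC, which differ in CFTR in the gut, acute-phase transcripts and Lcn2 stood higher in CFTR-KO in many classes. In B-like cells Lcn2 was at 469 ± 621 CPM in CFTR-KO and 4.89 ± 4.47 in CFTR-KO-GC, and Orm1, a plasma glycoprotein of the acute phase, at 564 ± 506 and 73.4 ± 29.9. In cholangiocyte-like cells H2-Eb1 was at 695 ± 804 CPM against 32.97 ± 4.80, and Krt17 at 6.45 ± 2.43 against 29.8 ± 8.10. The immediate-early transcription factor gene Fosb was at 376 ± 63.0 CPM in CFTR-KO and 1338 ± 183 in CFTR-KO-GC. It belongs to a list of immediate-early and heat-shock genes set as a sign of dissociation and RNA quality, of which 3 of 28 were above 0 here (median −0.60) and 5 of 28 against WT (−0.31) in the blocked fit.

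Without covariates edgeR called 0 genes in this comparison, in cholangiocyte-like cells or in any other class. Of 118630 pairs 3339 had an unadjusted p under 0.05, a share under the 0.05 expected with no differences. In cholangiocyte-like cells 967 of 13793 genes did, a share above it. DESeq2 called 321, and 224 in cholangiocyte-like cells. Without covariates and without CFTR-KO-GC replicate 1 edgeR called 2 pairs, and without CFTR-KO replicate 2, CFTR-KO replicate 3 or WT replicate 3 it called 1. The smallest p-values without covariates belonged to Lcn2 in smooth muscle-like (log2 fold change 5.62 ± 0.76, edgeR adjusted p 0.118) and Kupffer-like cells (5.88 ± 1.03, 0.816), Ly6d in vascular endothelial-like cells (3.63 ± 0.51, 0.42), and BC016579 and Bcl2 in hepatocyte-like cells (both 0.475). The blocked fit called 222 pairs and 134 genes in cholangiocyte-like cells, 92 higher and 42 lower. With version and sex as terms these were 57 and 1. The cholangiocyte-like count in the blocked fit was 20 without CFTR-KO replicate 1, 645 without CFTR-KO replicate 2 and 0 without CFTR-KO replicate 3. Without CFTR-KO-GC replicates 1, 2 and 3 it was 0, 0 and 11, and without WT replicates 2 and 3 it was 7 and 2. Over all classes it was 1529 without CFTR-KO replicate 2, 43 without CFTR-KO replicate 3, 57 and 115 without CFTR-KO-GC replicates 1 and 3, and 379 and 115 without WT replicates 1 and 3.

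In the blocked fit of cholangiocyte-like cells, H2-Eb1 rose by 3.77 ± 0.56 (edgeR adjusted p 0.0375), H2-Aa by 4.03 ± 0.67 (0.0463), Slpi by 5.16 ± 0.88 (0.0479) and the lysosomal protease gene Ctss by 3.33 ± 0.53 (0.044). Ccl5 rose by 2.58 ± 0.31, Cxcl9 by 5.43 ± 0.93, Fabp5 by 1.36 ± 0.20, Slc4a4 by 0.89 ± 0.15, and the acute-phase genes Hpx by 2.35 ± 0.35 and Orm2 by 5.41 ± 0.87, for which free hepatocyte RNA is open. Ccl5 was among the leading genes of the natural killer-like cluster, Ctss of the Kupffer-like and Slpi of the mesothelial-like cluster, so free RNA is open for them too. Krt17 fell by 2.23 on the log2 scale, Krt19 by 0.99, Kcnn4 by 0.89, Pkm by 0.93, Tbxas1 by 2.94 and Smim5 by 3.27. Fosb fell by 1.85 and the transcription factor gene Klf4 by 1.12. Each of these genes moved the same way in 3 of 3 pairs. With version and sex as terms Krt17 (adjusted p 0.00715) was the 1 gene called in this class. The folds of the other genes named here stayed about as large, with H2-Eb1 at 3.81 ± 0.61 (adjusted p 0.0799), H2-Aa at 4.14 ± 0.71 (0.0811), Slpi at 5.33 ± 0.94 and Fosb at −1.79 ± 0.28, and most errors were larger, so the lost calls do not show that version or sex explains the differences. Among the genes called in this class by the blocked fit, 73 were higher in CFTR-KO against both WT and CFTR-KO-GC, and 27 were lower in both. The comparisons share the CFTR-KO libraries and no unchanged groups were simulated for this pair, so how much of the overlap those libraries bring is not known.

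In other classes the blocked fit called Lcn2 in B-like (6.74 ± 0.54, edgeR adjusted p 1.75e-05), smooth muscle-like (5.81 ± 0.40, 1.19e-05), sinusoidal endothelial-like (5.90 ± 0.41, 0.000113), plasmacytoid dendritic-like (5.65 ± 0.64, 0.000151), natural killer-like, dendritic type 2-like, Kupffer-like and T-like cells. Its CFTR-KO means in these classes were 187 to 469 CPM, against 19642 CPM in cholangiocyte-like cells, so free RNA is open for these calls too. Orm1 was called higher in 7 classes, among them B-like (2.82 ± 0.34), dendritic type 1-like (2.66 ± 0.26) and smooth muscle-like cells (2.92 ± 0.40). Hp, Hpx and Fgl1, which hepatocytes secrete, were called in several of the same classes, and free RNA is open for them and for Orm1. The metallothionein genes Mt1 and Mt2 rose by 3.68 ± 0.39 and 3.42 ± 0.50 in B-like cells. Free RNA is open for them, and for the Spp1 call that follows, since Spp1 was a leading gene of cholangiocyte-like clusters. Dendritic type 2-like cells had higher Spp1 (1.58 ± 0.23) and the interferon-induced genes Ifi47 and Gbp7, and lower Tnf (−1.47 ± 0.22, adjusted p 0.0284), Ptgs2 (−1.32 ± 0.21) and Clec12a (−1.48 ± 0.24). With version and sex as terms all 6 of these calls in dendritic type 2-like cells were lost, with adjusted p-values from 0.0587 (Gbp7) to 0.28 (Spp1), at folds of −1.44 ± 0.26 for Tnf and 1.28 ± 0.31 for Spp1. So were Mt1 (3.46 ± 0.59, 0.0975) and Mt2 (3.29 ± 0.78, 0.416) in B-like cells, Lcn2 in Kupffer-like (5.78 ± 0.78, 0.112) and T-like cells (4.93 ± 0.73, 0.0623), the Fgl1 calls, Hp in B-like (0.224) and dendritic type 1-like cells (0.0559), and Hpx in B-like (0.224), dendritic type 1-like (0.0559) and natural killer-like cells (0.145). The folds given here, apart from that of Spp1, moved by less than their errors in the blocked fit, and the errors grew, so these losses do not show that version or sex explains the differences either. Lcn2 in the other 6 classes and Orm1 in all 7 still passed. Orm1 and Orm2, and Mup11 and Mup20, have close copies in the genome, so the split of UMIs between copies is uncertain.

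Between CFTR-KO-GC and WT few genes were called, which does not show that few differed. In simulated cholangiocyte-like data the fit without covariates recovered 0% of genes raised 2-fold in CFTR-KO against WT. Without a filter on low counts 143 of 286825 pairs were called, and with the block on numbers 2 and 3 alone 41. Each of these settings called 1 gene in cholangiocyte-like cells. Neither was checked on simulated counts, so their calls do not show that more differed. Gm20186 was at 0.13 ± 0.02 CPM in cholangiocyte-like cells of CFTR-KO-GC and 25.3 ± 10.8 in WT, the 1 gene called without covariates (log2 fold change −7.49 ± 0.64, edgeR adjusted p 0.0224). Over all classes 1628 of 118630 pairs had an unadjusted p under 0.05, and in cholangiocyte-like cells 92 of 13793 genes. Both shares lie under the 0.05 expected with no differences. Leaving out any 1 of CFTR-KO replicates 2 and 3, CFTR-KO-GC replicates 1, 2 and 3 or WT replicates 2 and 3 left 0 calls in this class. The blocked fit called 6 pairs and DESeq2 10. Beyond Gm20186, the blocked fit called Ptprb, an endothelial phosphatase gene, lower in hepatic stellate-like cells (3.46 ± 4.52 against 368 ± 351 CPM in WT, adjusted p 0.00296). In portal fibroblast-like cells it called Cyp4a10 lower (−2.45 ± 0.31) and Cftr higher, at 21.1 ± 11.5 CPM against 0.45 ± 0.79 (4.80 ± 0.59, adjusted p 0.0319). Ptprb, Cyp4a10 and Cftr are transcripts of endothelial cells, hepatocytes and cholangiocytes, so free RNA is open for them. For Cftr the source cells differed less, at 210 ± 161 CPM in CFTR-KO-GC and 86.9 ± 54.3 in WT in cholangiocyte-like cells. Free RNA alone would thus need a larger cholangiocyte share in the CFTR-KO-GC sums, and no such share was estimated. With version and sex as terms the calls of Ptprb (−7.86 ± 0.89 before, −7.40 ± 1.49 after, adjusted p 0.3) and Cyp4a10 (−2.45 ± 0.34 after, 0.0532) were lost, and that of Cftr was kept (0.0421). Leaving out 1 library moved the blocked count to 17, 48 and 15 without CFTR-KO replicates 1, 2 and 3, to 10 and 23 without CFTR-KO-GC replicates 1 and 2, and to 17 without WT replicate 2; in cholangiocyte-like cells the blocked fit called 0 without WT replicate 3.

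Cftr, the targeted gene (ENSMUSG00000041301, chromosome 6, 18170687 to 18322768), encodes a chloride and bicarbonate channel and was still detected in cholangiocyte-like cells of the knockout. Its level was 356 ± 266 CPM in CFTR-KO, 210 ± 161 in CFTR-KO-GC and 86.9 ± 54.3 in WT. The labels name an insertion and stop allele and the assay reads the 3' ends of transcripts, so remaining tags do not speak to channel protein. The 3 comparisons gave exact 2-sided permutation p-values of 0.3 (CFTR-KO against WT), 0.5 (CFTR-KO against CFTR-KO-GC) and 0.5 (CFTR-KO-GC against WT), where 0.1 is the smallest possible. Without covariates the log2 fold change of CFTR-KO against WT was 2.04 ± 1.07 (edgeR adjusted p 0.844), in the blocked fit 1.77 ± 0.26 (0.0289), and with version and sex as terms 1.83 (0.0631). Within Cell Ranger 5.0.1, CFTR-KO stood at 55.6 CPM, CFTR-KO-GC at 25.8 and WT at 25.5, 1 library each. Within 7.1.0 the values were 451 and 562 in CFTR-KO, 277 and 326 in CFTR-KO-GC, and 107 and 129 in WT.

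Gm20186 (ENSMUSG00000106874, a lincRNA gene on chromosome 6, 18845910 to 18848207) lies near Cftr and was close to 0 in both CFTR-null groups. In cholangiocyte-like cells it fell from 25.3 ± 10.8 CPM in WT to 0.16 ± 0.14 in CFTR-KO (−7.09 ± 0.60 without covariates, edgeR adjusted p 0.0206). In gamma-delta T or innate lymphoid-like cells it fell from 440 ± 302 to 1.05 ± 1.07 CPM (−8.13 ± 0.83, adjusted p 0.00708). The cholangiocyte-like call was lost without CFTR-KO replicate 2 or 3, any of the CFTR-KO-GC replicates, or WT replicate 2 or 3, each leaving 0 calls in this class. The call of Gm20186 in gamma-delta T or innate lymphoid-like cells, CFTR-KO against WT, was lost without CFTR-KO replicate 2 (adjusted p 0.206) or CFTR-KO replicate 3 (0.0857).

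**Figure D3:**
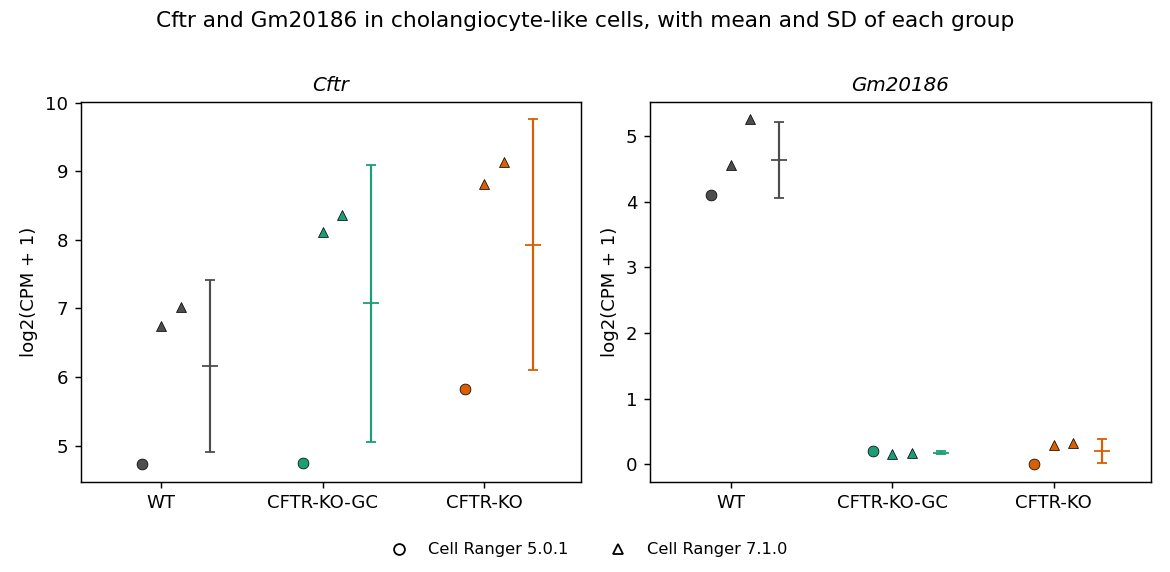
Levels of Cftr and Gm20186 per library and by group; circles are Cell Ranger 5.0.1 and triangles 7.1.0 libraries, and bars are the mean ± SD. Cftr averages 356 CPM in cholangiocyte-like cells of CFTR-KO and 86.9 in WT.

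As gene lists in cholangiocyte-like cells, CFTR-KO against WT in the blocked fit, all 8 MHC class II genes were above 0, with a median log2 fold change of 3.65; 5 were called over all genes and 8 when adjusted over the list alone. Antimicrobial genes had a median of 2.98, with 3 of 13 called and 12 when adjusted over the list alone. Interferon-stimulated genes had a median of 1.61 (1 of 28 called, 24 over the list alone), NF-kB targets and chemokines 1.43 (5 of 24, 14 over the list alone) and MHC class I genes 1.21 (0 of 15, 15 over the list alone). Of the lists of transcripts of other cell types, some had medians as high and some did not. Immunoglobulin genes had a median of 3.78 (4 of 7 called, 7 over the list alone), and haemoglobin genes 3.71 (0 of 5 called, 0 over the list alone). Abundant hepatocyte transcripts had a median of 0.26 (5 of 29 called, 9 over the list alone). Kupffer identity genes had a median of 0.37 (0 of 7 called, 2 over the list alone). Sinusoidal endothelial identity genes had a median of 0.40 (2 of 9 called, 7 over the list alone). The haemoglobin list did not pass with the preset correlation either (camera adjusted p 0.227). The list of ductular genes had a median of −0.03 and a mean of 0.10. In the fit without covariates the medians were 4.30 for MHC class II, 4.70 for antimicrobial, 1.91 for interferon-stimulated, 1.37 for NF-kB and 1.48 for MHC class I genes, beside 3.92 for immunoglobulin, 3.15 for haemoglobin and 5.46 for 4 tested neutrophil transcripts. The full neutrophil and antimicrobial lists share Lcn2, S100a8, S100a9, Ngp, Camp and Ltf, so free RNA is open for the antimicrobial list as well. Against CFTR-KO-GC the medians in the blocked fit were 3.25 for MHC class II, 3.40 for antimicrobial, 1.19 for interferon-stimulated, 0.79 for NF-kB and −0.60 for immediate-early and heat-shock genes, of which 2 were called, and 12 when adjusted over the list alone. Immunoglobulin genes had a median of 1.93 there (1 of 7 called, 4 over the list alone) and abundant hepatocyte transcripts 0.93 (4 of 29 called, 12 over the list alone). Haemoglobin genes were at 0.74, Kupffer identity genes at 0.36 and sinusoidal endothelial identity genes at 0.29. Between CFTR-KO-GC and WT the MHC class II median was 0.55 and no list member was called over all genes. When adjusted over the list alone, 0 of 8 MHC class II genes, 4 of 7 immunoglobulin genes (median 1.84), 2 of 9 sinusoidal endothelial genes and 1 of 13 antimicrobial genes were called, and 1 in each of 4 other lists.

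With the preset correlation camera called 312 of the list tests without covariates, but 2 with an estimated correlation, and the blocked fit with an estimated correlation called 3. None of these calls was in cholangiocyte-like cells, where the blocked adjusted p-values with an estimated correlation were 0.174 for MHC class II, 0.194 for antimicrobial, 0.27 for interferon-stimulated and 0.24 for NF-kB genes in CFTR-KO against WT. The 3 calls, all for CFTR-KO against WT, were cytotoxic effector genes in T-like cells (median 0.48, adjusted p 0.0441), interferon-stimulated genes in plasmacytoid dendritic-like cells (0.70, 0.0474) and immediate-early and heat-shock genes in smooth muscle-like cells (−0.50, 0.0299).

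**Figure D4:**
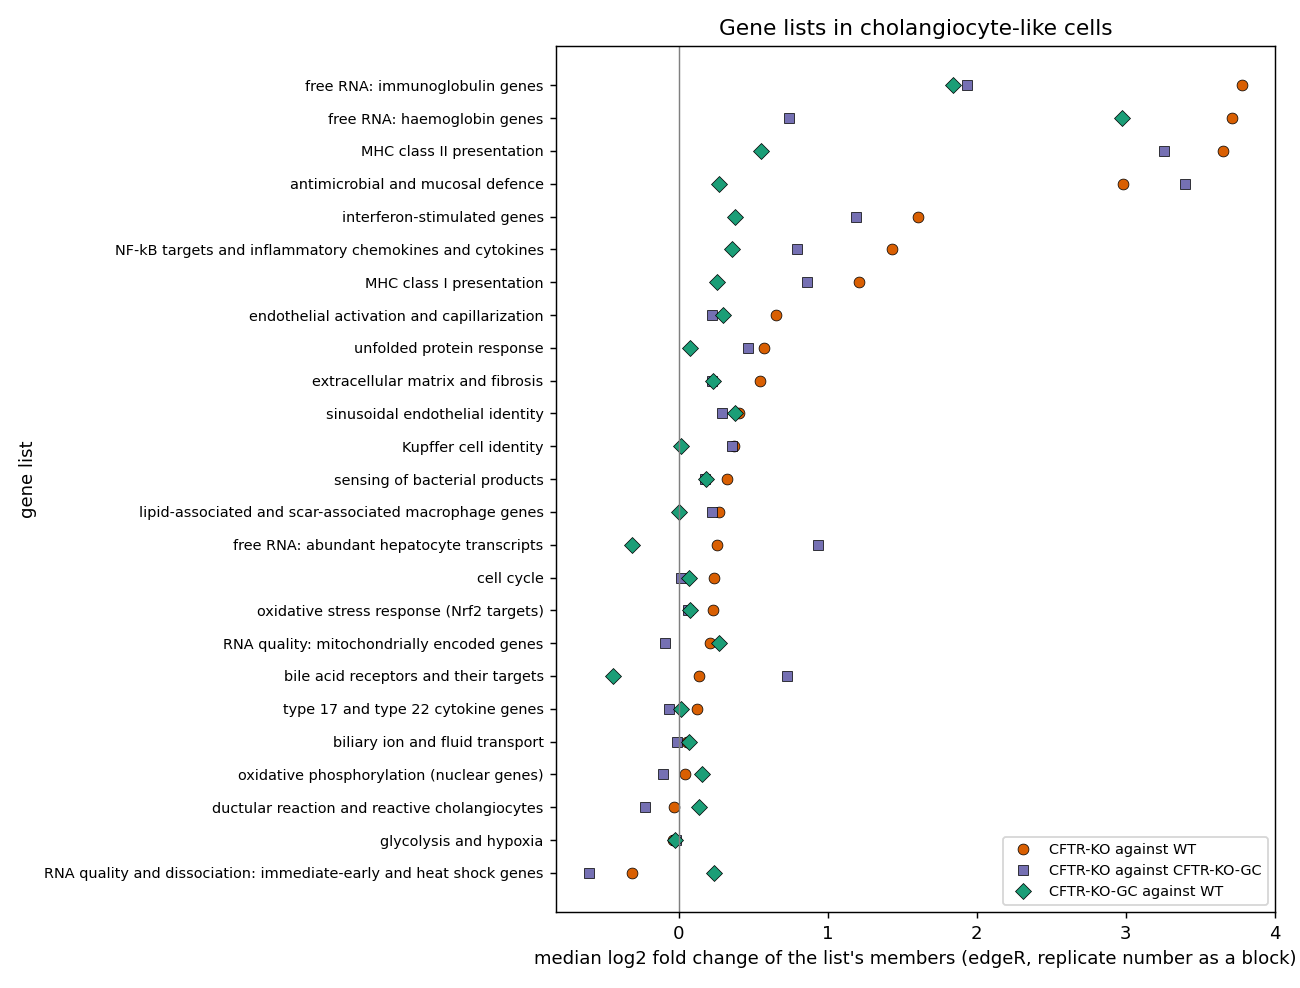
Median log2 fold change of each gene list in cholangiocyte-like cells for the 3 comparisons, from the fit with the replicate number as a block. The MHC class II list stands at 3.65 for CFTR-KO against WT and 0.55 for CFTR-KO-GC against WT.

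Across genes of cholangiocyte-like cells, the folds of CFTR-KO against WT and of CFTR-KO-GC against WT correlated at 0.401, and genes are not independent replicates. Simulated unchanged groups sharing the WT libraries gave 0.509. The covariance was 0.092 against 0.060 in the simulations, and part of it may come from the shared WT libraries, which with 3 of them cannot be divided into separate controls of 2.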

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

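Among the tests in this part, the rise of acute-phase over other hepatocyte transcripts, the search for a mislabelled library, the interval of the odds ratio near Cftr, and the splits within Cell Ranger version were chosen after the results or the file headers were seen; the other bounds were set before the values they test. Groups of 3 libraries are too small to test for a single far-off library.

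Cells outside every named class were compared between groups, and 3 unnamed clusters had a higher share in every CFTR-KO library than in any WT library. A cycling lymphocyte cluster led by Ube2c, Top2a, Trbc2 and Ctla4 averaged 0.358% of kept cells in CFTR-KO, with no CFTR-KO library under 0.238%, no WT library above 0.156% and a CFTR-KO-GC mean of 0.124%. Another, led by Gzma, Pclaf and Nkg7, averaged 0.355% in CFTR-KO, with at most 0.064% in WT and a mean of 0.066% in CFTR-KO-GC. A small cluster led by Cftr, Pak3, Cldn4 and Klra5 averaged 0.092% in CFTR-KO and was at 0 in WT; it kept 21 cells after 133 predicted doublets were removed from it. With 3 libraries per group, 10% of unchanged clusters are expected to lie apart without overlap in 1 direction or the other.

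Acute-phase transcripts (Orm1, Orm2, Saa1, Saa2, Hp, Hpx, Fgl1 and Serpina3n) were higher in CFTR-KO than in CFTR-KO-GC in immune and stromal classes. A larger amount of unchanged hepatocyte RNA in CFTR-KO droplets would lift all hepatocyte transcripts alike. The 8 acute-phase transcripts rose over 27 other hepatocyte transcripts by a median of 1.57 on the log2 scale over the classes, against a bound of 0.5. But Orm1, Orm2, Saa1, Hp, Hpx and Fgl1 were among the genes called higher in this same comparison. A set that holds them would outpace the others in any case, so the rise cannot decide on that explanation. The amount itself differed by pair. In T-like cells the other hepatocyte transcripts were at 15703 CPM in CFTR-KO replicate 1 and 20028.5 in CFTR-KO-GC replicate 1. Acute-phase transcripts were at 6700 and 957 there, so a larger amount does not account for that pair in these cells. Cholangiocyte-like cells went the other way in number 1, at 15286 and 10641.5. In T-like cells of number 2 the others were at 25715 and 6379, and of number 3 at 20768 and 13641, so a larger amount stays open there. Without CFTR-KO replicate 1 the rise was 0.704. Free hepatocyte RNA of a changed makeup remains open and may be the source, since the rise differed from that in hepatocyte-like cells by a median of −0.244, inside a bound of 1, with classes from −0.421 to 0.42. The study's own grouping, gut CFTR, stays open and was not separated from this.

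Gm20186, close to Cftr on chromosome 6, was near 0 in both CFTR-null groups. A strain segment carried with the targeted allele would be expected to shift its neighbours too. Within 10 Mb of Cftr, 5 of 370 gene and class pairs moved 1 way in both comparisons against WT at an unadjusted p under 0.05, and 63 of 5631 on the rest of the chromosome, a ratio of shares of 1.21 against a bound of 2. The exact 95% interval of the odds ratio was 0.378 to 3.004 (Fisher's exact p 0.61, with pairs that are not independent), so a wide segment stays open with so few pairs. Of those 5 pairs, 3 lay within 1 Mb of Cftr: Gm15594 at 0.18 Mb in cholangiocyte-like cells (log2 fold changes 1.78 and 1.90, unadjusted edgeR p 0.000674 and 0.000463), Met in the same cells (0.33 and 0.48) and Cav1 in sinusoidal endothelial-like cells (−1.31 and −1.06). A narrow segment and a local effect of the targeted allele both stay open, and a variant in Gm20186 itself was not tested. No single library stood out as exchanged between WT and a CFTR-null group. By this gene 0 libraries were out of place, with WT at 16.2, 30.3 and 47.0 CPM over all cells and the others at 0.477 to 1.47. Gm20186 was picked because it parts the labelled groups, so this count was close to fixed and does not exclude an exchange. An exchange of whole groups, such as WT with CFTR-KO-GC, would also leave 0 out of place. Nor can these values show an exchange between CFTR-KO and CFTR-KO-GC.

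MHC class II genes were higher in CFTR-KO cholangiocyte-like cells, summing to 9710, 859 and 2564 CPM in the CFTR-KO libraries and 145 to 292 CPM elsewhere. RNA of B, dendritic or Kupffer cells would bring their other markers. Those reached a median of 0.033 of the level needed, against a bound of 0.33, and 0.18 in CFTR-KO replicate 2, the highest of the 3, which argues against such RNA as the whole source. The rise does not rest on CFTR-KO replicate 1 alone, since without it the median log2 fold change was 2.83 against 3.65 with it, a ratio of 0.774. Expression by the cholangiocyte-like cells may be the source, as a hypothesis found and tested on the same data; no list test with an estimated correlation called it. Which cholangiocyte-like cells were recovered stays open as well, since cluster 7 held 1956 cells of CFTR-KO replicate 1 against 1 WT cell and 3 CFTR-KO-GC cells, and immunoglobulin transcripts rose in the same sums.

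Other groupings of the same libraries were tested for as many calls. For each pair of groups 10 splits exist, too few for a share under 0.05. CFTR-KO against WT called 2 pairs and the highest other split 2, in 2 of the 10 splits with as many. CFTR-KO against CFTR-KO-GC called 0, so all 10 splits had as many, and the highest other called 637, a split with CFTR-KO replicate 1 and CFTR-KO-GC replicates 1 and 2 together, which points to structure among the libraries. CFTR-KO-GC against WT called 1, with 4 splits as high and a highest other of 3. In cholangiocyte-like cells the real splits called 1, 0 and 1 and no other split called any, with 1, 10 and 1 splits as high. Where the split parts all pairs, the highest others were 0, 0 and 1.

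For the test over all 3 groups, chance could not be excluded without covariates: the real grouping called 1 gene, 20 of 100 splits gave as many, and the highest other gave 11239. That split and 5 others put the 5.0.1 libraries together and called 9714 to 11239, so the 5.0.1 libraries stand strongly apart from the others. These splits cannot tell the Cell Ranger version from anything else that the number 1 libraries share. With the version as a term, the real grouping called 260, and 4 of the 90 splits with 1 library of version 5.0.1 per group gave as many, a share under 0.05. The 5 other splits that kept the CFTR-KO libraries together called 147 to 526, the highest, and the 84 remaining splits called at most 46. That share rests on splits that ignore the pairing. Of the 36 splits that part all numbers as the real one does, 2 gave as many, a share not under 0.05, so chance is not excluded among them. Their highest other called 318, and the highest without the CFTR-KO libraries together called 4.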

How the results depend on the processing

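The fits with Cell Ranger version, with version and sex, on 7.1.0 libraries alone, from uncorrected components, the blocked leave-one-out counts and the blocked estimated correlation were chosen after seeing the data; the cause was not tested for any change below unless stated. Counts are given in the order CFTR-KO against WT, CFTR-KO against CFTR-KO-GC and CFTR-KO-GC against WT, and those of the plain fit were 2, 0 and 1 over all classes and 1, 0 and 1 in cholangiocyte-like cells. DESeq2 called 388, 321 and 10 (cholangiocyte-like 268, 224 and 3), the replicate block 257, 222 and 6 (234, 134 and 1), the block on numbers 2 and 3 alone 127, 181 and 41 (78, 28 and 1), the version term 294, 275 and 6 (284, 210 and 1), version with sex 40, 57 and 5 (29, 1 and 1) and the 7.1.0 libraries alone 22, 16 and 5 (17, 4 and 1). Without a filter on low counts the counts over all classes were 384, 507 and 143. CFTR-KO against WT fell to 1 with only 2 groups in the fit (cholangiocyte-like 0), to 1 with at least 50 cells, and to 0 with equal cell numbers (cholangiocyte-like 0); with the hepatocyte covariate it was 5, and CFTR-KO against CFTR-KO-GC 1. Adjusting over all classes together left 0 calls against WT in either null group, cholangiocyte-like cells included. Uncorrected components gave 10 for CFTR-KO against CFTR-KO-GC and 2 for CFTR-KO-GC against WT, and doublets kept gave 2 for the latter. Leaving out each library in turn gave 0 to 2 in each comparison over all classes and 0 to 1 in cholangiocyte-like cells. With the block it gave 10 to 1858, 43 to 1529 and 7 to 48 (cholangiocyte-like 1 to 755, 0 to 645 and 0 to 1), and with the version term, without CFTR-KO replicate 1 or 2 only, 64 to 533, 72 to 507 and 7 (59 to 483, 4 to 389 and 1). The test over 3 groups went from 1 to 315 without the filter, 223 with the block and 260 with the version. Class shares called were 1, then 3 with doublets kept, with TMM or with the version, 5 at resolution 0.5 or with immune or other cells alone as the denominator, 0 by exact permutation and 0 to 8 leaving out a library. List calls went from 312 to 487 without the filter, 2 with an estimated correlation, 1 with fry and 3 with block and estimated correlation. The Cftr log2 fold change of CFTR-KO against WT passed with the block (1.77, adjusted p 0.0289), with the version (1.77, 0.0219) and on 7.1.0 alone (2.10, 0.0264), but not with version and sex (1.83, 0.0631) or by DESeq2 (2.03, 0.503). It was 1.54 to 2.54 leaving out a library, 0.24 to 1.27 against CFTR-KO-GC and 0.80 to 1.79 for CFTR-KO-GC against WT. Directions reversed for Jchain in cholangiocyte-like cells, CFTR-KO against CFTR-KO-GC, with the hepatocyte covariate (−0.25, adjusted p 0.888) and for the T-like share of CFTR-KO against WT among immune cells alone (−0.001, 0.998). Among single named results, 2912 values under alternatives chosen before the data were examined kept direction and call, 282 passed that had not, and 27 no longer passed. Most of these results were not called by the plain fit, so keeping the call mostly meant staying uncalled. Adjusting over all classes together, which removed the plain calls, still left 126 values counted as kept and 3 as no longer passing. The count of kept values is therefore no measure of how stable the calls are. In simulated cholangiocyte-like data the plain fit recovered 0% of genes raised 2-fold in CFTR-KO against WT and 2.5% against CFTR-KO-GC, so small differences are beyond it here.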

Other observations

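Pancreatic acinar-like cells numbered 683 in CFTR-KO replicate 1 and at most 14 in any other library. Low-UMI droplets carrying hepatocyte transcripts, left unnamed, were 36.3 ± 20.6% of kept cells in WT, 12.4 ± 13.1% in CFTR-KO and 31.07 ± 14.5% in CFTR-KO-GC.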
